A study of Mus musculus with 15 samples.

How the data were processed

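Gastrocnemius muscle from 8 male floxed wild-type mice (controls) and 7 male mice with a skeletal muscle-specific knockout of Cpt1b was profiled. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, 500 ng per sample went into library construction, and barcoded SOLiD SAGE libraries were prepared for the SOLiD sequencing system. In this method a short tag beside a restriction site near the 3' end of each transcript is sequenced, so a count stands for a tag and does not scale with transcript length. Genes without such a site, isoforms that share a 3' end and relatives with the same tag cannot be measured or told apart. The labels count as many mice as libraries in each group, so each library was taken as a separate animal.

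The authors deposited a table of raw tag counts per gene symbol for the 15 libraries and a second table of normalized values. Per the submitters' processing notes, DESeq2 (version not given) was used, with the genome builds mm10 and GRCm38.p1. The aligner, the tag-to-gene counting and the annotation release were not given in the sources used here. The count table deposited by the authors holds 13602 gene symbols and 360 empty lines, which were dropped and hold no counts. The smallest total of a gene over the libraries was 22 and each gene had counts in at least 6 libraries, so genes with low counts appear to have been left out before deposit by a rule the sources do not state. The normalized table deposited by the authors holds signal values equal to the raw counts divided by 1 size factor per library (largest relative deviation 5.4e-10), and these factors matched DESeq2's median-of-ratios factors recomputed here (largest relative difference 6.6e-11). The symbols matched between the tables for 13601 genes. The raw counts were used for all tests, and the authors' size factors entered as an alternative scaling.

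Symbols were matched to the GENCODE M21 annotation of GRCm38, the build named by the submitters. Of the 13602 symbols 12392 matched directly and 944 through a single synonym, and 13238 obtained a position. A tag was predicted for 13227 symbols (97.2%) as the 27 bases starting at the CATG site nearest the 3' end, CATG being the usual anchoring site of SAGE. The labels do not name the enzyme, and the predicted tags served only for a check of GC content.

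Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (robust dispersion, TMM scaling, low-count filter filterByExpr with its minimum count of 10), with the group as the only term and Benjamini-Hochberg adjustment at 0.05. The filter left 11062 genes and removed 2540. The biological coefficient of variation was 0.291. Standard errors are the log2 fold change divided by the square root of the F statistic. The level of Cpt1b was also compared by an exact permutation test over the 6435 splits of the libraries. Log2 CPM used a prior count of 2. The differences of library measures between groups were tested by two-sided exact permutation tests.

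Gene lists were fixed before the data were examined. The 20 lists were mitochondrial fatty acid oxidation, PPAR target genes of muscle, peroxisomal fatty acid oxidation, triglyceride synthesis with lipolysis and lipid droplets, glucose transport with glycolysis and glycogen, pyruvate oxidation and the TCA cycle, oxidative phosphorylation, branched-chain and other amino acid catabolism, the integrated stress response with mitokines, the unfolded protein response with chaperones, mitochondrial biogenesis and dynamics, the slow-twitch and the fast-twitch muscle programs, muscle proteolysis with autophagy and glucocorticoid response, denervation and regeneration, antioxidant and NRF2 target genes, fatty acid and cholesterol synthesis, insulin and AMPK signalling, the circadian clock, and extracellular matrix and fibrosis. A further 10 lists held markers of adipocytes, macrophages, lymphocytes and granulocytes, endothelium, fibroblasts, smooth muscle and pericytes, erythroid cells, Schwann cells, tendon and satellite cells. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1, on voom log2 CPM, preset inter-gene correlation of 0.01), adjusted over each family of lists. Beside it stood camera with a correlation estimated from the data and fry. With an estimated correlation 11 of the 13 calls held, and the slow-twitch and extracellular matrix lists did not pass.

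The text names, by a rule fixed in advance, Cpt1b, Chkb, Cpt1a, Cpt1c, Fgf21 and Myl1 whatever their result, the 12 genes with the largest positive and the 12 with the largest negative fold change among genes past the threshold with a mean of at least 20 raw counts, and up to 4 called members of each gene list with the smallest adjusted p, or the member with the smallest p where none passed. Of the genes this rule chose, 2 are not reported here.

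Other settings tried were RLE scaling, library size alone, the authors' size factors, no low-count filter, a stricter filter (mean of at least 20 counts), DESeq2 1.42.0, limma voom with quality weights, a non-robust dispersion, the replicate number as a block, a subset by the numbers in the sample descriptions, and each library left out in turn. After the data were examined, fits without control replicate 7 and knockout replicate 4, with the first surrogate variable (sva 3.50.0) as a covariate, and with each library's trend with tag GC content removed were added. Per-library means of the lists were also compared after the data were examined.

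The tests were tested on simulated counts for this comparison, drawn for 11062 genes from the real means, dispersions and library sizes with 200 changed genes. The quasi-likelihood test called 16% of genes changed 1.5-fold, 58% of those changed 2-fold, 94% at 3-fold and 96% at 4-fold, each of 50 genes, and 3.65% of its calls were unchanged genes. With no gene changed it called 0 genes. The simulated genes varied independently of each other, unlike those of the real libraries, which differed along shared components. The simulated rates therefore need not hold for the real libraries. A planted trend with GC content gave a correlation of 0.641 between fold change and tag GC across 10855 genes, and -0.0126 after the correction. That correction removed the planted trend itself and did not estimate a trend from the counts. It therefore does not check the estimated trend that was removed from the real libraries.

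The closest pair of libraries, control replicates 1 and 2, differed by 12.1 times the sampling noise (chi-square per degree of freedom), so no library was treated as a repeat of another. No per-sample column was left out.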

Results

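Gene expression was measured in the gastrocnemius, a calf muscle of mainly fast-twitch fibres, of male mice that lacked Cpt1b in skeletal muscle and of male wild-type mice carrying the floxed gene. Cpt1b is the muscle form of carnitine palmitoyltransferase 1, the outer-membrane enzyme through which long-chain fatty acids enter the mitochondrion as acylcarnitines. The comparison asked which transcripts differ in muscle when this step is removed. There were 7 knockout and 8 control libraries, each made by SAGE, in which a short tag near the 3' end of each transcript is sequenced and counted. The series text and the sample titles describe chow feeding, for 12 to 14 weeks, whereas the diet field of all 15 samples reads 45% HFD. The field was the same in both groups. Total counts ran from 8334436 in control replicate 1 to 19397255 in knockout replicate 4, with a mean of 12517704 ± 2421091 (SD, n = 8) in controls and 12708521 ± 3168093 (SD, n = 7) in knockouts (exact permutation test, two-sided p = 0.901). Levels below are CPM, tag counts scaled by the TMM-adjusted library total (mean ± SD, n = 8 controls and n = 7 knockouts), and fold changes are log2 values of knockout minus control with their standard errors.

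Cpt1b tags were lower in the knockout libraries and were not absent from them. The gene lies on chromosome 15 from 89416405 to 89425863 (GRCm38, protein-coding). Its level was 7.64 ± 3.17 CPM in controls (4.44 to 13.1) and 3.79 ± 1.64 CPM in knockouts (1.10 to 6.46). The log2 fold change was -1.03 ± 0.31 (SE), with an edgeR adjusted p of 0.103 over all genes tested. As a single gene fixed in advance it differed between the groups by an exact permutation test on log2 CPM (two-sided p = 0.00389, 6435 splits). The mean of 70.9 tags per library limits the precision of this value. DESeq2 placed the same change past the threshold, with an adjusted p of 0.0314, and so did leaving out control replicate 7, with an edgeR adjusted p of 0.0487. The labels do not say which part of the gene was deleted. A tag near the 3' end may lie outside that part, and then the level does not check the genotype labels. Cpt1a, the liver form of the enzyme, stood at 4.59 ± 2.18 CPM in controls and 7.92 ± 3.98 CPM in knockouts. The log2 difference of 0.78 ± 0.30 did not pass over all genes tested (edgeR adjusted p = 0.248, unadjusted p = 0.0178). Cpt1a belongs to the mitochondrial fatty acid oxidation list below and passed when adjusted over that list alone. Chkb, Cpt1c and Fgf21 were not analysed here.

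The gene lists of mitochondrial fatty acid oxidation and of triglycerides and lipid droplets were higher in knockout muscle (camera adjusted p = 1.08e-30 and 6.85e-06, and 0.0003 and 0.000696 with an estimated correlation). More single genes were higher than lower. Of 11062 genes tested, 240 passed an adjusted p of 0.05, 185 higher and 55 lower in the knockout. The change was at least 2-fold in 93 of the higher genes and 13 of the lower genes. The knockout and control libraries did not overlap in 132 of the 11062 tested genes, where chance gives 0.0311% of genes, and 119 of the 132 were among the 240 called. Among the highest changes were BC048679 (chromosome 7, 81494275 to 81498281), which rose from 8.60 ± 2.94 to 112 ± 40.9 CPM (log2 3.69 ± 0.26), and Chrna2, a nicotinic acetylcholine receptor subunit, which rose by 3.10 ± 0.23. Igsf21, an immunoglobulin superfamily protein, rose by 3.04 ± 0.32, the potassium channel subunit Kcnv2 by 2.71 ± 0.24, and Acsf2, an acyl-CoA synthetase family member, by 2.38 ± 0.25. Gm5595, matched through a synonym to a zinc-finger gene on chromosome 7, rose from 77.9 ± 7.43 to 417 ± 78.4 CPM (log2 2.42 ± 0.13). The small GTPase Rab15 rose by 2.42, Tmem171 by 2.46 and Arhgdig by 2.57. Gm14964 (log2 3.74) and LOC101055930 (log2 3.41) had control levels of 0.279 ± 0.200 and 0.338 ± 0.222 CPM, so their folds rest on few control tags. Piwil2, a piwi-family protein, was higher by 2.39 ± 0.59 with an SD in knockouts above its mean (7.98 ± 10.03 CPM). Knockout replicates 1, 2 and 7 carried the Piwil2 difference (27.9, 14.8 and 5.98 CPM), while the other 4 knockouts (1.47 to 2.01 CPM) lay near the highest control (1.97 CPM), and without knockout replicate 1 the log2 difference was 1.617 (adjusted p = 0.114).

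Gm5091 (chromosome 17, 15231581 to 15247917) fell furthest, from 12.5 ± 6.0 CPM in controls to 0.829 ± 0.328 CPM in knockouts (log2 -3.90 ± 0.35). Ddit4l, an inhibitor of mTORC1 signalling, was the most abundant of the 12 genes with the largest decreases and fell from 999 ± 239 to 397 ± 102 CPM (log2 -1.33 ± 0.19). Dkk3, a secreted glycoprotein of the Dickkopf family, fell by 1.67, the potassium channel subunit Kcng4 by 1.42, the secretin receptor Sctr by 1.43 and the glutathione-binding protein Lancl1 by 1.27. Leptin (Lep) fell from 4.55 ± 2.78 to 1.27 ± 0.928 CPM and the imprinted gene Nnat from 7.14 ± 6.07 to 1.84 ± 1.53 CPM, both with wide spread. Cntnap2 (log2 -1.11), Cilp2 (-1.06), Wisp1 (-1.04) and the calcineurin regulator Rcan1 (-1.03) completed this set.

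Of the measured genes of mitochondrial fatty acid oxidation, 15 of 19 rose and none fell. All 19 had a positive fold change and passed when adjusted over the list alone, and their median log2 fold change was 1.20. Decr1, the mitochondrial dienoyl-CoA reductase (chromosome 4, 15917240 to 15945507), rose from 94.9 ± 17.3 to 319 ± 57.1 CPM (log2 1.75 ± 0.14, adjusted p = 8.4e-07). Acadl, the long-chain acyl-CoA dehydrogenase, rose from 129 ± 29.7 to 386 ± 65.8 CPM. Cpt2, which re-forms acyl-CoA inside the mitochondrion, rose from 69.2 ± 11.4 to 178 ± 36.8 CPM. Hadha, a subunit of the trifunctional protein, rose from 337 ± 21.7 to 667 ± 86.6 CPM. In each of these 4 genes every knockout library lay above every control library. Acadl (chromosome 1, 66830839 to 66863277) lies close to Myl1 (66924295 to 66945404) and to Lancl1 (67000517 to 67038872), which was called lower. Whether a local difference at that place contributed to the change of Acadl was not tested. The list was higher than other genes by camera (adjusted p = 1.08e-30; adjusted p = 0.0003 with an estimated correlation).

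**Figure D1:**
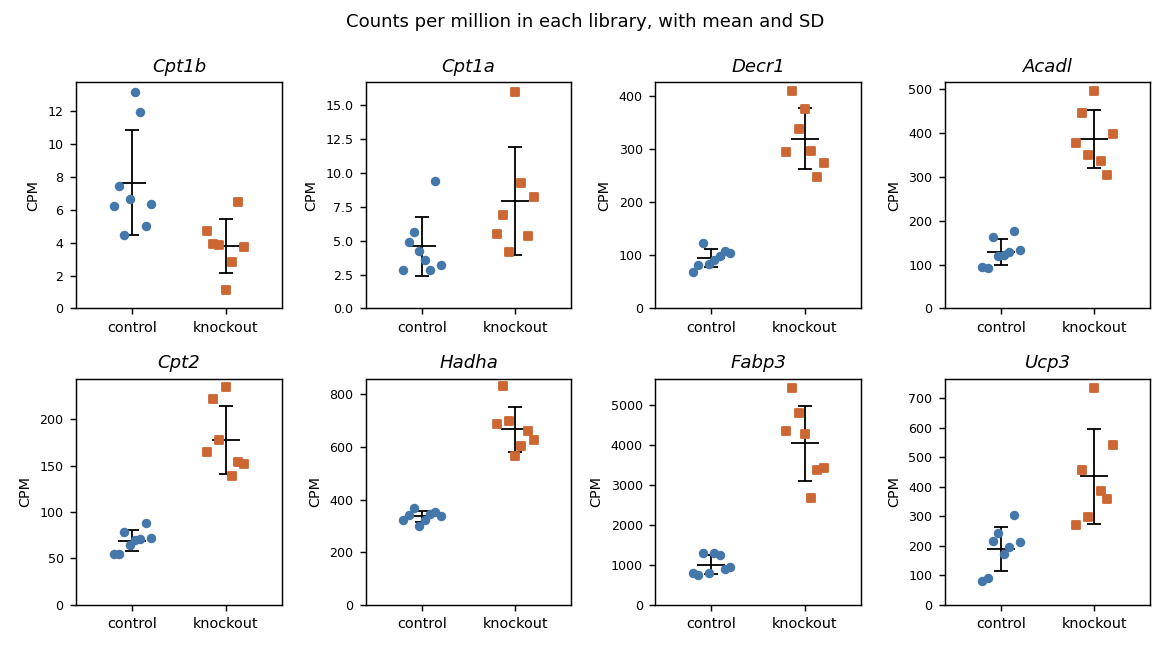
Each panel plots 1 gene, with CPM on a linear axis from 0 for the 8 control libraries (circles) and 7 knockout libraries (squares), and the bars give the mean and SD of each group. Decr1, Acadl, Cpt2, Hadha and Fabp3 do not overlap between the groups, whereas Cpt1b, Cpt1a and Ucp3 do.

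Target genes of the lipid-sensing PPAR receptors in muscle rose in 17 of 23 cases, 20 when adjusted over the list alone, with a median log2 fold change of 1.12 (camera adjusted p = 7.96e-32). This list shares 6 genes with the oxidation list and 2 with each of the peroxisomal and triglyceride lists. It shares 1 gene with each of the pyruvate, antioxidant and integrated stress response lists, so these lists are not independent of it. With an estimated correlation the camera adjusted p was 0.0003 for the PPAR targets. It was 0.000696 for both the peroxisomal and the triglyceride lists below. Fabp3, the fatty acid binding protein of heart and muscle (chromosome 4, 130308595 to 130315463), rose from 1000 ± 241 to 4037 ± 943 CPM (log2 2.01 ± 0.18). Acot2, a mitochondrial acyl-CoA thioesterase (chromosome 12, 83987861 to 83993873), rose from 73.6 ± 17.5 to 365 ± 88.7 CPM, and its tags are uncertain because closely related thioesterase genes can share sequence. Of 18 peroxisomal oxidation genes 5 rose, 7 when adjusted over the list alone (camera adjusted p = 7.19e-08). They included Cat, the hydrogen peroxide-degrading catalase (log2 1.49 ± 0.13), the transporter Abcd3 (0.66 ± 0.10) and Ech1, a dienoyl-CoA isomerase (2.04 ± 0.43). Of 22 genes of triglyceride synthesis, lipolysis and lipid droplets 6 rose, 7 when adjusted over the list alone (camera adjusted p = 6.85e-06). The lipid droplet protein Plin5 rose from 9.17 ± 2.66 to 28.6 ± 6.23 CPM and Dgat2, which makes triglyceride from diglyceride, from 36.4 ± 11.5 to 135 ± 43.0 CPM. The glycerol acyltransferase Gpam rose by 0.77 and the triglyceride lipase Pnpla2 by 0.75.

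Lists of other mitochondrial pathways were higher by camera, with fewer of their members past the test. With an estimated correlation the camera adjusted p was 0.0125 for oxidative phosphorylation and 0.000754 for pyruvate and the TCA cycle. It was 0.0003 for amino acid catabolism and 0.00178 for biogenesis. Of 63 oxidative phosphorylation genes 4 rose, 9 when adjusted over the list alone, 56 had a positive fold change and the median was 0.37 (camera adjusted p = 1.03e-10). The respiratory chain subunits Uqcrfs1 (log2 0.67), Uqcrc2 (0.57), Sdhb (0.82) and Sdhd (0.53) rose. Of 32 genes of pyruvate oxidation and the TCA cycle 4 rose, 14 when adjusted over the list alone (median 0.32, camera adjusted p = 6e-09). Sdhb and Sdhd belong to both lists, and the other members that rose were Pdk4, the kinase that inhibits pyruvate dehydrogenase (1075 ± 250 to 2331 ± 471 CPM), and Pdp2, the phosphatase that activates it (1.58 ± 0.499 to 2.87 ± 0.523 CPM). Of 30 amino acid catabolism genes 3 rose, 12 when adjusted over the list alone (median 0.32, camera adjusted p = 6.38e-09), namely Acat1, which acts in ketone and isoleucine breakdown (log2 0.94), the branched-chain dehydrogenase subunit Dbt (0.61) and the ketone-body enzyme Oxct1 (0.58). Of 27 genes of mitochondrial biogenesis and dynamics 2 rose, 4 when adjusted over the list alone (camera adjusted p = 0.000193), and these were the nuclear receptors Esrrb (log2 1.00) and Pparg (0.42). The counts of members that rose depended on single libraries, while the camera calls of these 4 lists held in each fit without 1 library. For oxidative phosphorylation the count was 14 without control replicate 7, 1 without knockout replicate 2, and 2 without control replicate 1, 2, 4, 5 or 6 or knockout replicate 3, 5 or 7. For pyruvate and the TCA cycle it was 12 without control replicate 7, 1 without knockout replicate 2 or 5, and 2 without control replicate 1, 2, 4, 6 or 8 or knockout replicate 4 or 7. For amino acid catabolism it was 6 without control replicate 7, 5 without knockout replicate 6 and 2 without knockout replicate 2. For biogenesis it was 5 without control replicate 7, and 1 without any other single library except knockout replicate 4, without which it stayed at 2. With the first surrogate variable as a covariate, and without control replicate 7 and knockout replicate 4 (both chosen after the data were examined), the counts that rose were 14 and 10 for oxidative phosphorylation, 14 and 11 for pyruvate and the TCA cycle, 12 and 5 for amino acid catabolism and 5 and 4 for biogenesis.

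Genes of glucose transport, glycolysis and glycogen did not pass as a group (camera adjusted p = 0.771), although 3 of 30 rose, 4 when adjusted over the list alone. Fbp2, the muscle fructose bisphosphatase, which acts against glycolysis (chromosome 13, 62836877 to 62858422), rose from 121 ± 34.0 to 549 ± 129 CPM (log2 2.18 ± 0.21). Ldhb, the lactate dehydrogenase subunit of oxidative tissue, rose by 1.20 and the glycogen branching enzyme Gbe1 by 1.17. With the first surrogate variable as a covariate 5 of this list rose.

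**Figure D2:**
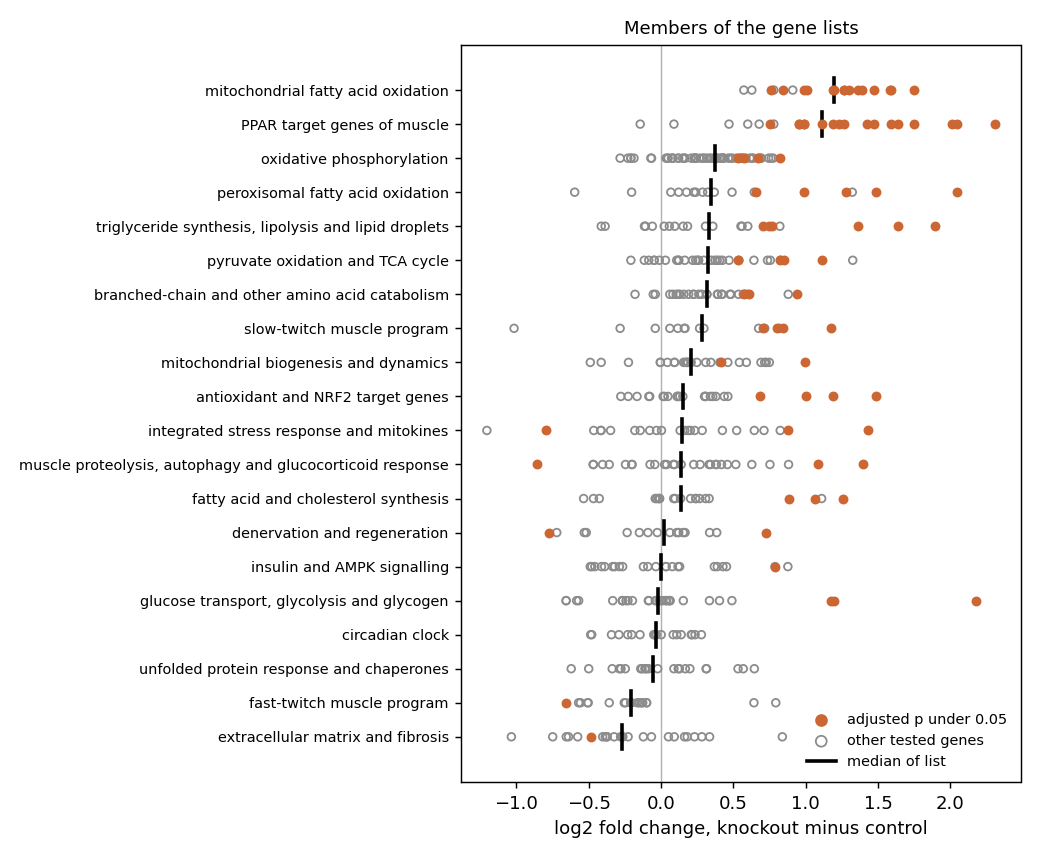
Each row is a gene list and each circle a tested member at its log2 fold change, knockout minus control, on the horizontal axis. Filled circles passed an adjusted p of 0.05 and the vertical bar is the median of the list, which was 1.20 for mitochondrial fatty acid oxidation, 0.37 for oxidative phosphorylation and -0.21 for the fast-twitch program.

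The slow-twitch list was higher and the fast-twitch list lower. With an estimated correlation the camera adjusted p of the fast-twitch list was 0.0161. Of 16 slow-twitch genes 4 rose, and 7 were higher and 1 lower when adjusted over the list alone (median 0.28, camera adjusted p = 0.000324). That call was lost with an estimated correlation (adjusted p = 0.0816 with an estimated correlation). The 4 were Atp2a2, the calcium pump of slow and cardiac muscle (433 ± 121 to 776 ± 131 CPM), its inhibitor Pln (log2 1.18), the calcium buffer Casq2 (0.80) and the oxygen store myoglobin, Mb (3093 ± 653 to 5048 ± 1373 CPM). These act in calcium handling and oxygen storage and are not parts of the contractile filament. The count was 2 without control replicate 5, 6 or 8 or knockout replicate 2, 3 or 7. Of 18 fast-twitch genes 1 fell, 2 when adjusted over the list alone, and 16 had a negative fold change (median -0.21, camera adjusted p = 0.00172). The gene that fell was Tnnt3, the fast troponin T (3121 ± 338 to 1983 ± 305 CPM). Calls in the fast-twitch list went both ways in other fits, with 2 higher and 1 lower without control replicate 7 and 2 higher and 3 lower with the first surrogate variable as a covariate. Myl1, the fast myosin light chain, whose level did not pass the test, had a log2 difference of -0.36 ± 0.20 (adjusted p = 0.448). The 10 most abundant genes took 28.9% ± 1.22 of counts in controls and 25.9% ± 1.39 in knockouts (SD, n = 8 and n = 7, two-sided exact permutation p = 0.0014, adjusted p = 0.00606 over 6 library measures).

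Antioxidant and NRF2 target genes rose in 4 of 25 cases, 5 when adjusted over the list alone (camera adjusted p = 2.18e-05, and 0.000754 with an estimated correlation). They were Cat, the mitochondrial uncoupling protein Ucp3 (190 ± 74.4 to 434 ± 160 CPM), the glutathione transferase Gsta4 (log2 1.00) and the quinone reductase Nqo1 (0.69), and the count was 2 without knockout replicate 2 or without knockout replicate 7. Cat also belongs to the peroxisomal list and Ucp3 to the PPAR list. Of 21 genes of fatty acid and cholesterol synthesis 3 rose, 4 when adjusted over the list alone (camera adjusted p = 0.015, and 0.042 with an estimated correlation). They were the desaturase Scd2 (55.8 ± 8.36 to 134 ± 38.6 CPM), the transcription factor gene Srebf1 (log2 0.89) and Insig1, which restrains it (1.07). This call was lost when the 2 libraries farthest along the leading principal component, control replicate 7 and knockout replicate 4, were left out (adjusted p = 0.0532), a choice made after the data were examined. Of 25 extracellular matrix genes 1 fell, the metalloproteinase inhibitor Timp2 (log2 -0.49 ± 0.11), and 5 were lower and 1 higher when adjusted over the list alone. The count that fell was 4 without control replicate 7, 3 without knockout replicate 3, 2 without knockout replicate 4 or 6, and 0 without control replicate 6 or knockout replicate 1, 2 or 5. Without control replicate 4, 1 gene of the list was called higher and 1 lower. The list was lower by camera (adjusted p = 0.0014), but not with an estimated correlation (adjusted p = 0.259 with an estimated correlation) and not by fry (adjusted p = 0.113), and its mean log2 CPM in each library did not pass (5.255 ± 0.281 in controls and 5.064 ± 0.235 in knockouts, exact permutation p = 0.181, adjusted p = 0.269 over 29 lists).

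The remaining lists did not pass by camera. As a background for the counts of genes below, 1501 of all 11062 tested genes had an unadjusted p under 0.05 by edgeR. DESeq2 called 449 genes and voom 716. By the mean log2 CPM of a list in each library, a comparison chosen after the data were examined, the integrated stress response list was at 3.41 ± 0.0604 in controls and 3.53 ± 0.127 in knockouts (exact permutation p = 0.0232, adjusted p = 0.0395 over 29 lists) and the proteolysis list at 5.91 ± 0.111 and 6.09 ± 0.131 (exact permutation p = 0.0137, adjusted p = 0.0283). In the integrated stress response list (24 genes, adjusted p = 0.41) the pseudokinase Trib3 (log2 1.43) and the one-carbon enzyme Mthfd2 (0.88) rose and Ppp1r15a, which restores translation, fell by 0.80, and 2 were higher and 2 lower when adjusted over the list alone. Mthfd2 lost its call without control replicate 1, 2, 4, 5, 6 or 8 or knockout replicate 1, 2, 3 or 5, and Ppp1r15a without control replicate 6 or knockout replicate 7, while 2 of the list fell without control replicate 7. In the list of unfolded protein response and chaperones (22 genes, adjusted p = 0.934) 0 genes passed over all genes by edgeR (4 at an unadjusted p under 0.05, 3 by DESeq2 and 2 by voom), 2 were higher and 1 lower when adjusted over the list alone, and the mitochondrial chaperone Hspa9 had the smallest p (log2 0.53 ± 0.14, adjusted p = 0.0623). Over all genes, 2 were higher and 1 lower in this list without control replicate 7 and with the first surrogate variable as a covariate, 1 was lower without knockout replicate 3, 1 was higher without knockout replicate 6, and 2 were higher without both control replicate 7 and knockout replicate 4. In the list of proteolysis, autophagy and glucocorticoid response (29 genes, adjusted p = 0.152) Ddit4, an mTORC1 inhibitor (log2 1.40), and the transcription factor Cebpd (1.09) rose and the receptor Eda2r fell by 0.85, and 3 were higher and 1 lower when adjusted over the list alone. The count that rose here was 4 without control replicate 7, 3 without knockout replicate 6, 1 without control replicate 8 or knockout replicate 1 or 2, 0 without control replicate 1, 5 or 6 or knockout replicate 4 or 7, and 5 with the first surrogate variable as a covariate. In the list of denervation and regeneration (16 genes, adjusted p = 0.59) Chrna1, the muscle acetylcholine receptor alpha subunit, rose by 0.72 and the kinase Mylk4 fell by 0.77, the same 1 higher and 1 lower gene when adjusted over the list alone. With the tag GC trend removed Chrna1 lost its call (log2 0.725 ± 0.155 before and 0.666 ± 0.172 after, adjusted p = 0.0512). In the list of insulin and AMPK signalling (24 genes, adjusted p = 0.999) Tbc1d4, a regulator of GLUT4 traffic, rose by 0.79, and 2 were higher and 1 lower when adjusted over the list alone (over all genes, 2 rose without control replicate 3 or without control replicate 7, 1 fell without control replicate 5 or with the tag GC trend removed, and 2 rose and 2 fell with the first surrogate variable as a covariate). In the clock list (18 genes, adjusted p = 0.349) 0 genes passed by edgeR, over all genes or over the list alone (2 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by voom). The median and the mean fold change had opposite signs in the glucose list (-0.02 and 0.06), the unfolded protein list (-0.05 and 0.01), the denervation list (0.02 and -0.06), the insulin list (-0.0005 and 0.03) and the endothelial markers (0.07 and -0.02).

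Markers of tendon and of fibroblasts were lower in the knockout libraries by camera. Of 7 tendon markers 3 fell, 4 when adjusted over the list alone (median -0.72, camera adjusted p = 6.32e-05; adjusted p = 0.146 with an estimated correlation). They were Cilp2, Comp (log2 -0.79) and Chad (-0.72), all matrix proteins of tendon and cartilage. Of 11 fibroblast markers 1 fell, 2 when adjusted over the list alone (median -0.26, camera adjusted p = 0.0256; adjusted p = 0.233 with an estimated correlation), and it was the actin-severing protein Gsn (log2 -0.54). The fibroblast count was 2 without control replicate 7, 1 without control replicate 3 or 4 or knockout replicate 3 or 4, 0 without any other single library, 3 without both control replicate 7 and knockout replicate 4, and 0 with the tag GC trend removed. Comp, Chad and Gsn were named after their values were seen. Among 10 adipocyte markers 1 fell, Lep, also when adjusted over the list alone, and the median was -0.04 (camera adjusted p = 0.7), and Lep lost its call without control replicate 1, 2, 5 or 6 or knockout replicate 1, 2, 3, 5 or 7. Marker lists of macrophages (10 genes, median -0.28, adjusted p = 0.0804), endothelium (10 genes, 0.07, 0.891), smooth muscle and pericytes (8 genes, -0.28, 0.0804), erythroid cells (3 genes, -0.22, 0.692), Schwann cells (5 genes, 0.20, 0.891) and satellite cells (5 genes, -0.18, 0.329) did not pass, the values in each bracket being tested genes, median log2 fold change and camera adjusted p. In these 6 lists 0 of 41 genes passed by edgeR, over all genes or over the list alone (6 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by voom). Of all 11062 tested genes 1501 had an unadjusted p under 0.05 by edgeR. The lymphocyte and granulocyte list had 1 tested gene and was not tested.

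The libraries were also spread widely within each genotype. The first principal component of log2 CPM held 44.6% of the variance and the second 10.2%. Scores on the first were -12.1 ± 31.7 in controls and 13.9 ± 33.3 in knockouts (SD, n = 8 and n = 7, two-sided exact permutation p = 0.145, adjusted p = 0.218), and control replicate 7 (51.2) and knockout replicate 4 (76.2) lay farthest out in their groups. Of all 30 lists, mitochondrial fatty acid oxidation moved most along this component, with a median of 0.505 log2 units per SD of the scores over all libraries, and the PPAR targets moved by 0.312. Control replicate 7 had the highest control mean of the oxidation list (6.08 log2 CPM), below the lowest knockout mean (6.57, replicate 6). Scores on the second were -11.1 ± 10 in controls and 12.7 ± 12.1 in knockouts (exact permutation p = 0.00202, adjusted p = 0.00606). Without control replicate 7 the count of changed genes was 311 higher and 154 lower. The count of lower genes was 30 without control replicate 6 or without knockout replicate 2, 34 without knockout replicate 7 and 35 without control replicate 1.

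**Figure D3:**
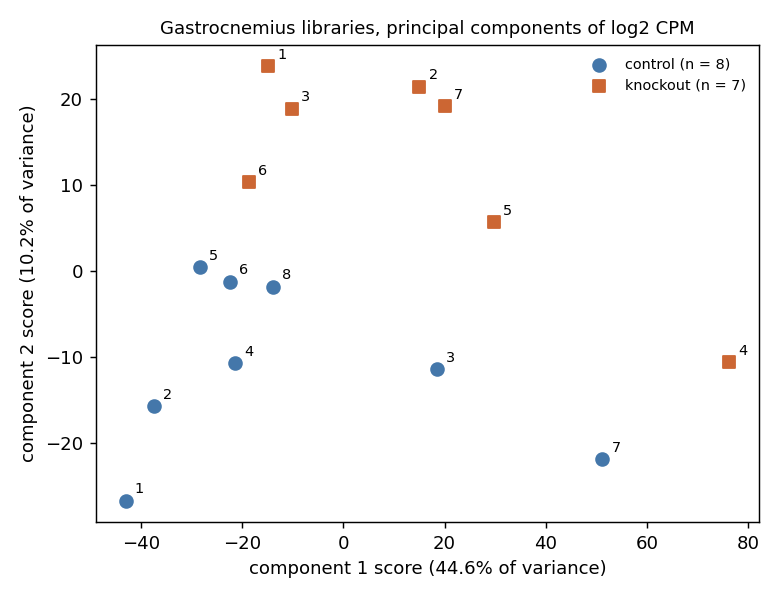
Scores of the 15 libraries on the first (horizontal, 44.6% of variance) and second (vertical, 10.2%) principal components of log2 CPM, unitless, with replicate numbers beside the points. Control libraries are circles and knockout libraries squares, and knockout replicate 4 sits at 76.2 and control replicate 7 at 51.2 on the first component.

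Of the 73 called genes chosen by the naming rule, 52 kept their call in each of the 15 fits that left out 1 library. The 21 that lost it at least once were Pparg, Sdhd, Insig1, Mb, Mthfd2, Pdp2, Piwil2, Casq2, Lep, Nnat, Cebpd, Rcan1, Uqcrc2, Nqo1, Ddit4, Wisp1, Timp2, Ppp1r15a, Sdhb, Ucp3 and Oxct1, with adjusted p up to 0.15 (Sdhd, without knockout replicate 2). Removing the tag GC trend, a choice made after the data were examined, ended 4 calls, those of Sdhd (log2 0.516, adjusted p = 0.0567), Oxct1 (0.454, 0.172), Pparg (0.327, 0.229) and Chrna1 (0.666, 0.0512), with a smaller fold in each. Sdhd and Pparg also lost their calls with RLE scaling, with the size factors of the authors and with no low-count filter, Sdhb, Mb and Insig1 with library size only, and Piwil2 by voom with quality weights and with the first surrogate variable as a covariate. In the subset by description number, which leaves out control replicates 1, 7 and 8, 15 calls ended, those of Piwil2, Nnat, Pdp2, Sdhd, Uqcrc2, Ppp1r15a, Mthfd2, Pparg, Pln, Casq2, Ddit4, Cebpd, Chrna1, Srebf1 and Insig1. With the replicate number as a block, in a fit without control replicate 8, 28 calls ended. They were those of Piwil2, Cntnap2, Wisp1, Rcan1, Abcd3, Gbe1, Sdhb, Pdp2, Sdhd, Uqcrfs1, Uqcrc2, Dbt, Oxct1, Ppp1r15a, Mthfd2, Pparg, Atp2a2, Pln, Casq2, Mb, Tnnt3, Cebpd, Chrna1, Gsta4, Nqo1, Srebf1, Insig1 and Timp2.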

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

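Among the tests in this part, the comparison of the component between genotypes and the correlation with total counts were chosen after the scores had been seen.

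In 162 groups of per-library values (2 groups for each gene named by the rule and reported here, or library measure), 6 had a highest or lowest library set apart from the rest by more than Dixon's 95% limit, where chance gives about 1 in 20 groups. Control replicate 7 was the lowest control for Oxct1 (gap of 0.619 of the range), Pparg (0.69) and Nqo1 (0.593). Control replicate 4 was the lowest control for Fbp2 (0.66) and control replicate 1 for Piwil2 (0.59). Knockout replicate 4 had the highest total count of the knockouts (0.632), 19397255 against 13073442 for the next.

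The first principal component held 44.6% of the variance and 84.4% of its own variance lay within the groups, with a difference between them of 26.0 that is smaller than 47.1, which is 0.5 of the narrower range within a group (exact permutation p = 0.1451), so genotype alone does not account for it. Thinning every library to 8334436 counts left 98.6% of the spread of the scores. Random thinning keeps the gene proportions of a library, so it speaks only to counting noise and not to other links with total counts. Removing each library's trend with tag GC content left 96.8% of the spread. Scores were higher in libraries with larger total counts over the 15 libraries (Pearson r = 0.751, permutation p = 0.00137; Spearman rho = 0.514, p = 0.0527, 100000 permutations, a single relation, so no adjustment), but without the 2 libraries whose totals lay farthest from the median, knockout replicate 4 and control replicate 7, r was 0.334 (p = 0.265), so the relation rests on those libraries. Within controls r was 0.782 (exact permutation p = 0.0203; rho 0.667, p = 0.0831) and within knockouts 0.828 (exact permutation p = 0.0444; rho 0.536, p = 0.236). RNA quality, library preparation and differences between animals, for which the labels give no measure, stay open.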

How the results depend on the processing

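The fits without 2 libraries, with a surrogate variable and with the tag GC trend removed were chosen after the data were examined, and the others before. The 185 higher and 55 lower genes stayed within 1.5 times under 7 other settings of scaling, filter, dispersion or tag GC content (170 to 191 higher, 46 to 58 lower), and under the subset by description number (148 and 47). DESeq2 called 305 and 144, including each of the 240 genes, and put Cpt1b past the threshold (log2 -1.035, adjusted p = 0.0314). Voom with quality weights called 453 and 263 (63.3% higher against 77.1%), with Cpt1b at -1.086 (adjusted p = 0.0124). The surrogate variable gave 419 and 199, with Cpt1b at -0.9873 (adjusted p = 0.0155), and kept 99.6% of the 240 genes. Leaving out control replicate 7 and knockout replicate 4 gave 255 and 148 (63.3% higher), with Cpt1b at -0.9428 (adjusted p = 0.0432), and kept 95.4%. The cause was not tested in these cases. Over all settings the adjusted p of Cpt1b ran from 0.0124 to 0.212.

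Leaving out 1 library gave 131 to 311 higher genes, 30 to 154 lower genes and a Cpt1b fold change of -1.204 to -0.856. Without control replicate 7 there were 311 higher and 154 lower genes, 66.9% higher, including each of the 240, and Cpt1b passed (adjusted p = 0.0487). Lower genes numbered 30 without control replicate 6, 30 without knockout replicate 2, 34 without knockout replicate 7 and 35 without control replicate 1.

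The labels share replicate numbers between the groups, but same-numbered libraries did not deviate together (correlations from -0.45 to 0.314), and 1 library correlated best with its own number. With the replicate block 98 genes were higher and 19 lower in 14 libraries, against 151 and 41 without it in the same libraries. Of the named genes called with all 15 libraries, 28 were no longer called. That count includes the effect of leaving out control replicate 8, which by itself ended 9 calls. The proteolysis list passed by camera with the block (adjusted p = 0.0288).

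Of the gene lists, 13 were called in each fit with a list test except the block (14), the estimated correlation (11) and the fits noted next. The lists were not tested with DESeq2 or with the tag GC trend removed. The slow-twitch list (adjusted p = 0.0816) and the extracellular matrix list (adjusted p = 0.259) did not pass with an estimated correlation, the latter did not pass by fry (adjusted p = 0.113), and fatty acid and cholesterol synthesis did not pass without the 2 libraries (adjusted p = 0.0532). The cause was not tested. No named gene reversed, and the medians of the 13 called lists kept their sign. The medians of the glucose, insulin, denervation, unfolded protein, clock, adipocyte, endothelial, erythroid, Schwann and satellite cell lists, which did not pass, took both signs over the settings. The test recovered 16% of simulated 1.5-fold changes, and 58% of 2-fold changes, so small changes were not detectable for many genes at this depth and number of libraries.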

Other observations

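The tests of the per-library list means and of the splits along the leading component were chosen after the data were examined.

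Of the 240 called genes 68 belonged to the 20 gene lists, 63 of them higher and 5 lower, and 172 belonged to none. Averaged over its 19 genes, mitochondrial fatty acid oxidation stood at 5.67 ± 0.257 log2 CPM in controls and 6.82 ± 0.191 in knockouts (SD, n = 8 and n = 7), with all 7 knockout libraries above every control library. The exact permutation p was 0.000155, the smallest that 6435 splits can give (adjusted p = 0.000751 over 29 lists). The same smallest p was found for the PPAR targets (6.13 ± 0.174 and 7.29 ± 0.185), triglyceride genes (4.64 ± 0.0864 and 5.05 ± 0.0919), pyruvate and TCA genes (7.10 ± 0.0847 and 7.48 ± 0.0959), amino acid catabolism (5.66 ± 0.0568 and 5.995 ± 0.0702) and antioxidant genes (5.07 ± 0.0901 and 5.37 ± 0.0352). In all, 17 of the 29 lists passed. The others higher in knockouts were peroxisomal oxidation (adjusted p = 0.00113), mitochondrial biogenesis (0.00113), oxidative phosphorylation (0.0025), fatty acid and cholesterol synthesis (0.0274), proteolysis (0.0283), the slow-twitch program (0.0288) and the integrated stress response (0.0395), each an adjusted p from the exact permutation test. The fast-twitch program was lower (11.8 ± 0.0939 and 11.6 ± 0.0836, exact permutation p = 0.00342, adjusted p = 0.00991), and so were fibroblast markers (6.69 ± 0.101 and 6.43 ± 0.242, exact permutation p = 0.016, adjusted p = 0.029). Tendon markers averaged 5.77 ± 0.319 in controls and 5.19 ± 0.372 in knockouts (exact permutation p = 0.00793, adjusted p = 0.0192). Smooth muscle and pericyte markers averaged 5.29 ± 0.152 and 5.06 ± 0.170 (exact permutation p = 0.00606, adjusted p = 0.016), whereas endothelial markers averaged 3.80 ± 0.164 and 3.77 ± 0.107 (exact permutation p = 0.68, adjusted p = 0.758).

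Of 100 splits of the 15 libraries into 7 and 8, 3 gave at least as many called genes as the real split with its 240, the real one included. That share is under 0.05, but it rests on 100 splits, and 2 of the others called far more genes than the real one. The number of called genes therefore does not exclude chance. The highest of the other splits called 2346 genes and the next 1575, while 93 splits called 0. Those 2 splits had the largest differences on the first principal component of the 100 (45.7 and 42.7, against 26.0 for the real split), but the third largest (42.0) went with 2 called genes and the fourth (38.0) with 0, so a difference along the component did not by itself give many calls, and what gave the calls in those 2 splits stays open. The fatty acid oxidation list differed most in the real split, by 1.15 log2 units, against 0.633 in the split with 2346 genes, 0.192 in the split with 1575 and at most 0.819 in any other split.

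The rise of the fatty acid oxidation genes was set against 4 other explanations. Without control replicate 7 and knockout replicate 4 their median log2 fold change was 1.228 (bootstrap 95% interval over the genes 0.86 to 1.33), and with the tag GC trend removed 1.179 (0.93 to 1.31), against 1.196 with all libraries. These values argue against those 2 libraries and the tag GC trend as the whole cause. Leaving out 1 high-scoring library of each group does not remove the difference between groups along the leading component, so that fit does not test the component itself. The list moved along the component by 0.505 log2 units per SD. Its median was 1.12 with the first surrogate variable, which correlated with the component (absolute Pearson r = 0.941), as a covariate. A larger share of slow-twitch fibres would raise slow-twitch genes at least as much, but their median was 0.282 (0.11 to 0.74). The expectation set in advance was for the contractile genes, whereas the whole list was used. The comparison covers slow-twitch genes only, and shifts among types of fast fibre were not tested. A share of adipose RNA would raise adipocyte markers, whose median was -0.0377 (-0.23 to 0.19). The bootstrap intervals resample the genes of a list and not the animals, so they do not measure the spread between animals. Adipoq (adiponectin), an abundant adipocyte transcript, had a log2 difference of 0.00 ± 0.32, which rested on knockout replicate 4 (78.79 CPM), since the other knockouts ran from 14.3 to 27.85 CPM and the controls from 20.66 to 42.28 CPM. A response of muscle to the loss of Cpt1b may explain the rise as a hypothesis, found and examined on the same libraries, and a change of diet or activity that went with genotype stays open.

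Each of the 20 chromosomes tested held called genes, but shares of whole chromosomes do not show whether called genes cluster locally. A segment of another strain carried along with the floxed Cpt1b gene could give differences near it only where the groups differ in that segment. The controls also carry the floxed gene, so this comparison says little about such a segment. Over all 11062 tested genes 1501 had an unadjusted p under 0.05 by edgeR, and DESeq2 called 449 genes and voom 716. Within 10 Mb of Cpt1b 0 of 136 tested genes were called by edgeR (17 at an unadjusted p under 0.05, 2 by DESeq2 and 4 by voom). Elsewhere 239 of 10723 were called (2.23%, Fisher's exact test p = 0.0781, odds ratio 0 with an upper 95% limit of 1.22). That limit lies above 1, and no conclusion about such a segment is drawn. No chromosome had a share of called genes that passed adjustment over the 20 tested (smallest adjusted p = 0.484). Segments elsewhere in the genome were not tested.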
